A study of Mus musculus with 7 samples.

How the data were processed

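Ribosome-bound RNA of cholinergic cells was measured by RNA sequencing in mouse ventral striatum. Translating ribosome affinity purification (TRAP) captures tagged ribosomes, together with the RNA on them, from the cells that carry the tag, here cells in which the Chat promoter is active. Each library pooled 6 ventral striata of 3 mice aged 8 to 12 weeks, on a C57/Bl6N background. Mice of both sexes were used, but not in every pool by their RNA. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were listed at 0 FPKM in WT2, WT3 and KO2. All mice carried 2 floxed alleles of S100a10, the gene of the protein p11. The 3 WT libraries came from littermates without Cre and the 4 KO libraries from mice with Cre driven by Chat. Groups and replicate numbers were taken from the sample titles. A replicate was therefore a pool of mice, and the p-values measured the spread between pools.

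Per the labels' protocols, 1 ng of purified RNA was amplified with the Ovation V2 kit and made into TruSeq V2 libraries. The submitters' processing notes name TopHat2 2.0.8, TopHat, Cufflinks 2.1.1, DESeq 1.10.1 and the genome build mm10, without the role of each. The annotation, the handling of strand and of reads with several matches, and the count table behind the authors' own test were not given in the sources used here. The expression values were FPKM (fragments scaled to gene length and library size) deposited by the authors for each library, rounded to 1 decimal, in 22016 rows with 21636 symbols. A value under 0.05 was therefore listed as 0.0. The authors also deposited a table of 113 genes with their mean FPKM per group, the fold of KO over WT, its log2 value, and a p-value with its adjusted form. Every adjusted p-value in that deposited table was at most 0.05. The authors' group means lay within 0.1 FPKM of the means of the library columns for 98 of the 98 genes compared, beside the pairs of library numbers and samples in the file header.

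FPKM is not a count, so the sequencing depth was unknown and neither counting intervals nor detection floors were given. Summed FPKM ran from 379417 to 511328 per library. The values were transformed to log2(FPKM + 1), and rows with a mean of at least 1 FPKM over the 7 libraries were tested, 10089 rows in all. KO and WT were compared with limma 3.58.1 in R 4.3.3 (eBayes with trend, two-sided), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are KO minus WT on the log2(FPKM + 1) scale, which understates the change of genes with low values. Means and SDs are of FPKM. For S100a10, an exact two-sided permutation test of the difference of mean FPKM over the 35 splits of 3 against 4 libraries was run as well, with the two-sided p taken as the doubled one-sided p. Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3 in Python 3.11.15.

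A total of 32 gene lists was fixed before the data were examined. The 25 lists with at least 3 tested rows were tested with camera (inter-gene correlation preset at 0.01), again with an estimated correlation, and with fry, and p-values were adjusted over the lists. Camera compares a list with the other tested rows, whereas fry and its mixed test do not. The named genes followed a rule that was also set before the data were examined. It took S100a10 first and then the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold whose groups did not overlap. It added up to 4 measured members of each list with the smallest unadjusted p, every member of the p11 list, and the 5 largest changes in either direction in the authors' deposited table. Predicted genes without a name were passed over in naming and stayed in the counts. Some genes that the rule took are not reported here, and they were left out of the search for single values that stood apart and of the counts of named genes; they stayed in the list tests.

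On simulated data built from the means and variances of the 10089 rows, with 200 rows changed in each of 5 draws, limma recovered 17% of the 1.5-fold, 79.4% of the 2-fold and 99.4% of the 4-fold changes, and 4.8% of its calls were false. A list moved by 0.5 on the log2 scale was found by camera at an adjusted p of 3.8e-22, with 0 of the other lists called. The simulated rows varied independently of each other. These rates therefore do not cover variation shared between genes or a single library that stands apart.

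Symbols were matched to the GENCODE annotation of mm10 for coordinates, transcript GC content and length, and 98.4% of the rows had a match. The share of a gene's 31-mers that also occur in transcripts of other genes was used to mark multi-copy genes, with a limit of 20%. The alternatives were other pseudocounts, other filters on low values, quantile normalization, median centring, limma without trend, with robust variances or with array weights, a replicate block, summed rows of a symbol, and each library left out in turn. Removal of trends with GC content and length, and a model term for libraries with Y-linked RNA, were added after seeing the data. A count-based test was not run, since the values are not counts. Libraries of a group were compared with each other, and no pair of libraries held identical values in more than 3.7% of the tested rows.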

Results

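The data were FPKM values of ribosome-bound RNA in 7 libraries, 3 WT and 4 KO, from cholinergic cells of the mouse ventral striatum. KO mice carried Cre under Chat control, which deletes the floxed S100a10, and WT mice were littermates without Cre. The design addressed which RNAs on the ribosomes of cholinergic cells differ between mice with and without the Chat-driven deletion of S100a10. Its product p11 is a partner of annexin A2 and of serotonin receptors. Cre came only with KO, so an effect of Cre itself cannot be told apart from one of the deletion. Cholinergic RNAs were abundant in every library. Chat, the acetylcholine-synthesizing enzyme, stood at 248 ± 51.9 FPKM in WT (SD, n = 3) and 205 ± 53.5 in KO (SD, n = 4), and Slc18a3, the vesicular acetylcholine transporter, at 543 ± 132 and 322 ± 40.8 FPKM. Between 9730 and 10247 rows per library reached 1 FPKM. Pearson correlations of log2 values between libraries, taken across genes, ran from 0.929 for WT1 with KO1 to 0.991 for WT2 with WT3.

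S100a10, the targeted gene on chromosome 3 (93555080 to 93564643, plus strand, mm10, ENSMUSG00000041959.14), fell in the KO libraries to 38.9% of its WT mean. The labels do not give the part of the gene that was floxed, so this level can include reads of exons that were not deleted. Its level was 329.5, 332.7 and 387.5 FPKM in WT1 to WT3 and 127.1, 138.8, 189.8 and 89.2 FPKM in KO1 to KO4. The means were 350 ± 32.6 (SD, n = 3) and 136 ± 41.5 FPKM (SD, n = 4), and the 4 KO values lay below the 3 WT values. The log2 fold change was -1.40 (SE 0.22, 95% confidence interval -1.89 to -0.91, limma adjusted p = 0.0098). The exact two-sided permutation p, the doubled one-sided p, was 0.0571, the smallest that 35 splits can give in this form. The limma call was lost without WT1 (-1.44, adjusted p = 0.063) and without WT2 (-1.44, adjusted p = 0.058).

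Of the other p11 partners, 6 could be tested and 0 of the 6 passed the threshold with limma, also at an unadjusted p under 0.05. Ctsb, the lysosomal protease cathepsin B, had the smallest p of them, with 104 ± 6.84 FPKM in WT and 128 ± 5.36 in KO (log2 fold change 0.29, limma adjusted p = 0.28). Cacna1d, Dlc1, Chrm4, Kcnk3 and Grm5 had log2 fold changes of -0.17, -0.09, -0.09, -0.06 and -0.02. Anxa2, Anxa1, Htr1b, Htr4, Plat, Trpv5 and Trpv6 were below the filter on low values, Htr1b with 0.2 to 2.3 FPKM across the libraries. Ahnak, Hltf, Htr1d, Asic1, Bad and Cacna1c were not analysed here. Adjusted over the list alone, S100a10 was the 1 member of the list that passed.

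Across all tested rows, 176 differed between KO and WT, 98 higher and 78 lower in KO, and these rows carried 167 symbols. The change was at least 2-fold in 56 of the higher and 28 of the lower rows. Predicted or unnamed genes made up 38 of the 176 rows, 32 of them higher in KO. At an unadjusted p under 0.05 limma found 1899 rows. WT and KO values did not overlap in 1755 rows, 17.4% of those tested, where chance gives 5.7%. The median log2 fold change of all tested rows was 0.03.

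Of the named genes, Cdr1 had the largest rise on the log2(FPKM + 1) scale, ahead of Bcor; with a pseudocount of 0.1, Onecut2 (3.49) and Adamts13, listed at 0.0 FPKM in WT, ranked above Cdr1 (3.46). Cdr1, a cerebellar degeneration-related gene on chromosome X (61184005 to 61185558), rose from 41.4 ± 12.2 FPKM in WT (SD, n = 3) to 452 ± 121 in KO (SD, n = 4), a log2 fold change of 3.43 (SE 0.24, limma adjusted p = 1.1e-05). The handling of strand was not given, so RNA from the opposite strand at Cdr1 cannot be told apart. Bcor, a corepressor of BCL6, also on chromosome X (12036740 to 12160355), rose from 14.5 ± 4.32 to 120 ± 30.7 FPKM (2.97, adjusted p = 2.3e-05). Gse1, a coiled-coil protein on chromosome 8, rose from 15.8 ± 3.8 to 109 ± 23.9 FPKM (2.71, adjusted p = 1.9e-05). Bahcc1, a BAH domain protein on chromosome 11, rose from 3.07 ± 0.95 to 22 ± 9.83 FPKM (2.41, adjusted p = 0.0033). Onecut2, a homeobox transcription factor on chromosome 18, rose from 0.433 ± 0.252 to 5.8 ± 2.58 FPKM (2.19, adjusted p = 0.0016).

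Adamts13, the protease that cleaves von Willebrand factor, was listed at 0.0 FPKM in the 3 WT libraries and at 7.0, 6.7, 4.5 and 4.7 FPKM in KO1 to KO4 (limma adjusted p = 2.1e-05). S100a1, a calcium-binding relative of p11 on chromosome 3 (90511034 to 90514392), rose from 1.77 ± 0.924 to 10.8 ± 1.59 FPKM (2.15, adjusted p = 0.0011). Prr12, Snhg1 and Tac2 completed the named genes higher in KO, with log2 fold changes of 2.1, 1.72 and 1.70. Snhg1, which hosts small nucleolar RNAs in its introns, rose from 17.2 ± 8.47 to 54.1 ± 9.52 FPKM, and Tac2, the neurokinin B precursor, from 0.8 ± 0.436 to 5.32 ± 3.26 FPKM. The WT values of Tac2 lay near the rounding step of the table.

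Nme7, a nucleoside diphosphate kinase family member on chromosome 1 (164304121 to 164437725), had the lowest fold change of the named genes and fell from 101 ± 14.6 FPKM in WT (SD, n = 3) to 2.82 ± 1.33 in KO (SD, n = 4), a log2 fold change of -4.79 (SE 0.25, limma adjusted p = 1e-06). Srsf4, a splicing factor on chromosome 4 (131873617 to 131901706), fell from 20.1 ± 3.97 to 0.825 ± 0.0957 FPKM (-3.51, adjusted p = 1e-06). Neither Nme7 nor Srsf4 was in the authors' deposited table, and an effect of the FPKM quantification on them stays open. Zfp352, a zinc finger gene, was listed at 4.9, 6.1 and 1.5 FPKM in WT1 to WT3 and at 0.0 in the 4 KO libraries (adjusted p = 0.0053), and 21.5% of its 31-mers occur in other genes. Mt3, a brain metallothionein, fell from 12.3 ± 1.68 to 3.5 ± 1.07 FPKM (-1.59, adjusted p = 0.0033). Rhov fell from 6.53 ± 0.666 to 1.62 ± 0.624 FPKM (-1.55, adjusted p = 0.0061). Agpat4, a lysophospholipid acyltransferase, fell from 28.2 ± 7.51 to 9.65 ± 2.39 FPKM (-1.45, adjusted p = 0.008). Lrrc47, Gfod2 and Cdkn2d, the last an inhibitor of cyclin-dependent kinases, followed with log2 fold changes of -1.32, -1.30 and -1.24.

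**Figure D1:**
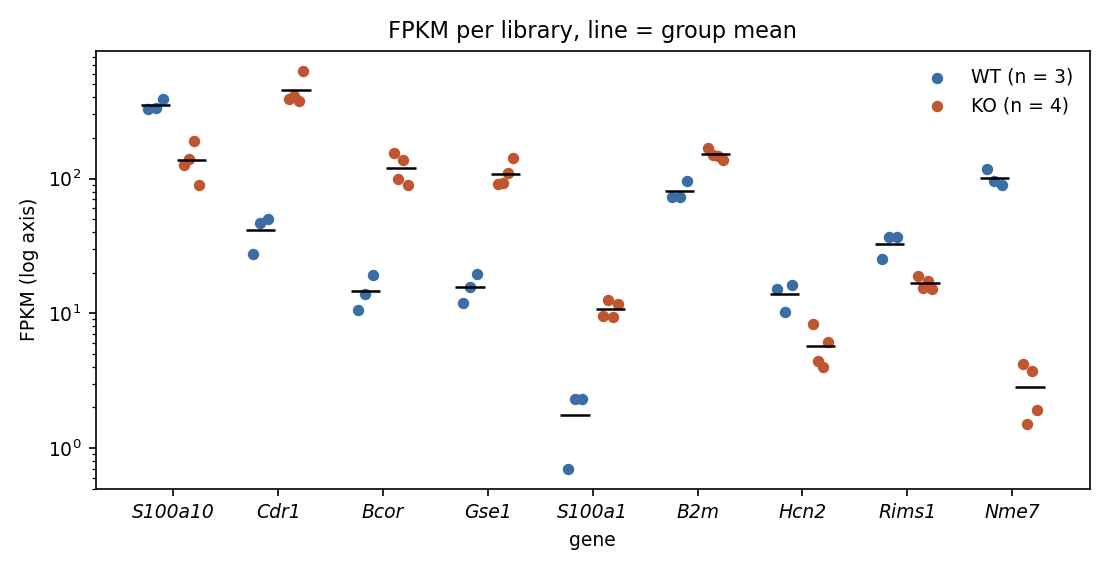
FPKM of 9 genes in each of the 3 WT and 4 KO libraries (points, log axis), with the group mean as a line. The KO values of S100a10 lay between 89.2 and 189.8 FPKM and the WT values between 329.5 and 387.5 FPKM, and in each of the 9 genes the groups did not overlap.

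The number of calls depended on single libraries. It was 44 without WT1, 28 without WT2, 75 without WT3, 376 without KO1, 56 without KO2, 97 without KO3 and 111 without KO4, and it was 133 with the trends in GC content and length removed. Of the 28 named genes that passed, 11 passed in all 7 fits with a library left out: Adamts13, Bahcc1, Bcor, Cdr1, Gse1, Mt3, Nme7, Onecut2, S100a1, Srsf4 and Zfp352. The call was lost in 1 such fit for Prr12 (without WT1), Rhov (without WT2) and Snhg1 (without KO2), and in 2 fits (without WT1 or WT2) for Agpat4, Gfod2, Lrrc47 and S100a10, with adjusted p of at most 0.079 in these 7 genes. Cdkn2d lost it without WT1, WT2, KO2 or KO4 (adjusted p up to 0.21), and Tac2 without WT1, WT2, WT3, KO3 or KO4 (up to 0.16), with GC and length trends removed (0.066), with a pseudocount of 5 (log2 fold change 0.78, adjusted p = 0.063), without a filter on low values (0.095), with the term for Y-linked RNA (0.077) and with the replicate block (0.19). The library numbers in the file header ran from 83 to 113 in WT and from 210 to 222 in KO, so that no range of numbers held both groups.

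Markers of cholinergic neurons gave 0 calls with limma over all rows, and 3 at an unadjusted p under 0.05. Of 13 tested members 5 had a positive and 8 a negative fold change, with a median of -0.12. Slc18a3 had the smallest p (log2 fold change -0.73, limma adjusted p = 0.092) and passed when adjusted over the list alone. With quantile normalization Slc18a3 passed over all rows (-0.77, adjusted p = 0.034). Chrm2, a muscarinic autoreceptor, and Lhx8, a transcription factor of cholinergic neurons, had fold changes of -0.37 and 0.26. The list tests gave adjusted p of 0.29 (camera) and 0.26 (fry), while fry's mixed test, which asks for change in either direction, called the list (adjusted p = 0.002). The mixed test does not compare the list with other genes, and 1899 of all 10089 tested rows had an unadjusted limma p under 0.05.

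Several markers of other striatal cells had their highest value in KO1. Sst, the somatostatin precursor of another interneuron class, stood at 5.67 ± 0.987 FPKM in WT and at 51, 6.7, 9.8 and 23.7 FPKM in KO1 to KO4 (log2 fold change 1.45, limma adjusted p = 0.16). Penk, Ppp1r1b and Drd1a, genes of medium spiny neurons, reached 50.7, 112 and 9.3 FPKM in KO1, and their means over all KO libraries were 27, 64.6 and 4.8 FPKM. Drd2, a marker of medium spiny neurons that cholinergic interneurons also express, stood at 553 ± 124 FPKM in WT and 685 ± 116 in KO. Mbp and Mobp, genes of myelin, stood at 33.5 and 12.8 FPKM in KO1, with KO means of 18.5 and 6.88 FPKM. None of the 11 medium spiny neuron, 6 other interneuron, 7 oligodendrocyte or 3 astrocyte markers passed, and the medians of these lists were 0.41, 0.36, 0.45 and 0.29 (camera adjusted p = 0.70, 0.53, 0.36 and 0.57; fry 0.94, 0.60, 0.60 and 0.40). Without KO1 the medians were 0.05, -0.16, 0.13 and 0.15, and camera placed the medium spiny neuron markers in the negative direction (adjusted p = 0.50). Without KO3 the medium spiny neuron and oligodendrocyte medians were 0.67 and 0.68, and without WT2 the astrocyte median was 0.13. At an unadjusted p under 0.05 limma found 1, 1, 0 and 0 of them. The interneuron marker was Sst, and the medium spiny neuron marker was Rasd2, lower in KO with 146 ± 14.8 FPKM in WT and 105 ± 20.4 in KO (-0.48, adjusted p = 0.17), and its lowest value was in KO1 (82.3 FPKM). Slc1a2, the astrocyte glutamate transporter, had a log2 fold change of 0.36. Glutamatergic neurons (Slc17a7, 0.40) and oligodendrocyte precursors (Pdgfra, 0.07) had 1 tested marker each. Endothelial and mural cells had Itm2a (0.39) and Rgs5 (-0.10), and ependymal and choroid plexus cells had Rsph1 (-1.18) and Ttr (0.73). None of these 6 genes passed over all rows, Rsph1 passed when adjusted over its list alone, and no blood cell marker reached the filter.

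Among HCN and potassium channels, Hcn2 was the 1 of 27 tested members that passed. Hcn2, a pore subunit of the hyperpolarization-activated current, fell from 13.9 ± 3.17 FPKM in WT (SD, n = 3) to 5.72 ± 2 in KO (SD, n = 4), a log2 fold change of -1.17 (SE 0.24, limma adjusted p = 0.036). Kcnip1 and Kcnj2 had fold changes of 1.16 and 0.99 and passed, with Hcn2, when adjusted over the list alone. The list as a whole had a median of 0.13 (camera adjusted p = 0.89). The Hcn2 call was kept in 1 of 7 fits with a library left out, the fit without KO1 (adjusted p up to 0.16 without each of the others), and was lost with GC and length trends removed (-0.75, adjusted p = 0.13).

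Of the vesicle release genes, Rims1, a scaffold of the presynaptic active zone, fell from 32.9 ± 6.5 to 16.8 ± 1.73 FPKM (-0.92, SE 0.17, limma adjusted p = 0.021). These values are of the Rims1 row with the smaller p, and the other of its 2 rows did not pass over all rows. Sv2a, a synaptic vesicle glycoprotein, had a fold change of -0.56 (adjusted p = 0.072). When adjusted over the list alone, 2 rows of Rims1 and that of Sv2a passed. The list median was -0.07 and its camera p was 0.022, adjusted 0.18. The Rims1 call was lost without WT2, WT3, KO2 or KO4 (adjusted p up to 0.13).

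Receptor genes gave 1 call. Gabrg3, a GABA-A receptor subunit, rose from 27.3 ± 2.97 to 45.2 ± 5.76 FPKM (0.70, SE 0.15, limma adjusted p = 0.044), and it was the 1 of 12 GABA receptor genes that passed, also when adjusted over the list alone. The Gabrg3 call was kept in 1 of 7 fits with a library left out, the fit without KO1 (adjusted p up to 0.2 without each of the others), and was lost with GC and length trends removed (0.62, adjusted p = 0.12). None of 17 sodium and calcium channels, 7 serotonin and dopamine receptors, 4 acetylcholine receptors or 14 glutamate receptors passed, over all rows or adjusted over the list alone, and 2, 0, 1 and 1 of them had an unadjusted limma p under 0.05. Cacna1a, a calcium channel of presynaptic terminals, had a log2 fold change of -0.64, Drd2 of 0.32, Chrna7 of 0.34 and Grik5 of -0.51. The 5 lists, GABA receptors first, had camera adjusted p of 0.53, 0.76, 0.53, 0.64 and 0.91. The sodium and calcium channels and the glutamate receptors had positive medians (0.04 and 0.10), while camera placed both lists in the negative direction.

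The list named for the SWI/SNF chromatin remodelling complexes had 10 negative and 4 positive fold changes among 14 members, with a median of -0.20. Smarce1 fell from 11 ± 0.964 FPKM in WT to 6.15 ± 0.759 in KO (-0.75, SE 0.16, limma adjusted p = 0.044). Smarca4, an ATPase of the complex, fell from 30.4 ± 4.1 to 18.6 ± 1.81 FPKM (-0.68, SE 0.15, adjusted p = 0.048). Smarcd3 and Smarcb1 had fold changes of -0.54 and -0.56 and passed, with the other pair, when adjusted over the list alone. The list did not pass with camera (p = 0.0024, adjusted p = 0.06, and adjusted p = 0.58 with an estimated correlation), and passed with fry (adjusted p = 0.05 after rounding up). With GC and length trends removed the Smarca4 call was lost (-0.45, adjusted p = 0.19). At the preset correlation camera called the list lower without WT3, KO1 or KO2 (adjusted p = 0.027, 0.012 and 0.044). With all libraries camera at that correlation also called it without a filter (0.015), at a mean of at least 5 FPKM (0.0099), with array weights (0.02) and with the term for Y-linked RNA (0.041). Smarce1 and Smarca4 each passed in 1 of 7 fits with a library left out, the fit without KO1 (limma adjusted p up to 0.2 and 0.23 without each of the others). The list was named SWI/SNF but also held Smarca1 and Smarca5, which belong to ISWI complexes.

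B2m, the light chain of class I antigen-presenting molecules, rose from 80.4 ± 12.8 to 151 ± 12.9 FPKM (0.91, SE 0.16, limma adjusted p = 0.015), the 1 of 11 interferon and antigen presentation genes that passed. H2-D1 and Oasl2 of the same list had fold changes of 0.47 and 0.38. The list median was 0.28 (limma camera adjusted p = 0.24). The B2m call was lost without WT1, WT2 or KO2 (adjusted p up to 0.12) and with GC and length trends removed (0.58, adjusted p = 0.089).

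Ribosomal protein genes had 53 positive and 26 negative fold changes among 79, with a median of 0.15 (camera unadjusted p = 0.02, adjusted p = 0.18). Rps25, of the small subunit, rose from 437 ± 10.9 to 885 ± 212 FPKM (0.99, SE 0.21, limma adjusted p = 0.044), and Rpl30 and Rpl22l1 had fold changes of 0.74 and 0.66. In Rps25, 27.4% of the 31-mers occur in other genes. At the preset correlation ribosomal proteins as a list were called higher without WT1, KO1 or KO2 (camera adjusted p = 0.0017, 5.9e-07 and 0.0077) and with array weights (0.00029), while the direction turned without KO4 and with the replicate block (median -0.01 in both, adjusted p = 0.87 and 0.89). With all libraries and an estimated correlation the adjusted p was 0.99. Respiratory chain genes split evenly, 41 with positive and 41 with negative fold changes, and had a camera adjusted p of 0.89. Ndufa13, a subunit of complex I, fell from 195 ± 28.5 to 109 ± 19.1 FPKM (-0.84, SE 0.18, adjusted p = 0.043). Rps25 passed in 1 of 7 fits with a library left out, the fit without KO1 (adjusted p up to 0.19 otherwise), and Ndufa13 lost its call without WT1, WT2, WT3, KO2 or KO4 (adjusted p up to 0.18). Mitochondrially encoded genes were not analysed here.

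S100 proteins and annexins other than p11 had 10 positive and 3 negative fold changes among 13 tested members, with a median of 0.28 (limma camera adjusted p = 0.29). S100a1 was the 1 member that passed over all rows. Anxa4 and Anxa11, with fold changes of 0.79 and -0.85, passed with it when adjusted over the list alone, both at means of at most 1.77 FPKM in either group.

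Of the 25 lists tested, camera called 0 at an adjusted p under 0.05 and 4 at an unadjusted p under 0.05. With an estimated correlation these counts were 0 and 1, and fry gave 1 and 5. Fry's mixed test called 7 lists: markers of cholinergic neurons, the SWI/SNF list, the unfolded protein and integrated stress response, p11 and its partners, vesicle release genes, the other S100 proteins and annexins, and interferon and antigen presentation genes (adjusted p from 0.002 to 0.014). It asks whether a list's members change at all and does not compare them with other genes. Over all 10089 tested rows, 1899 had an unadjusted limma p under 0.05. These calls therefore do not set the 7 lists apart from the other tested genes. The p11 list holds the targeted gene S100a10, its 1 member with an unadjusted limma p under 0.05, so its call says nothing about the partners.

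**Figure D2:**
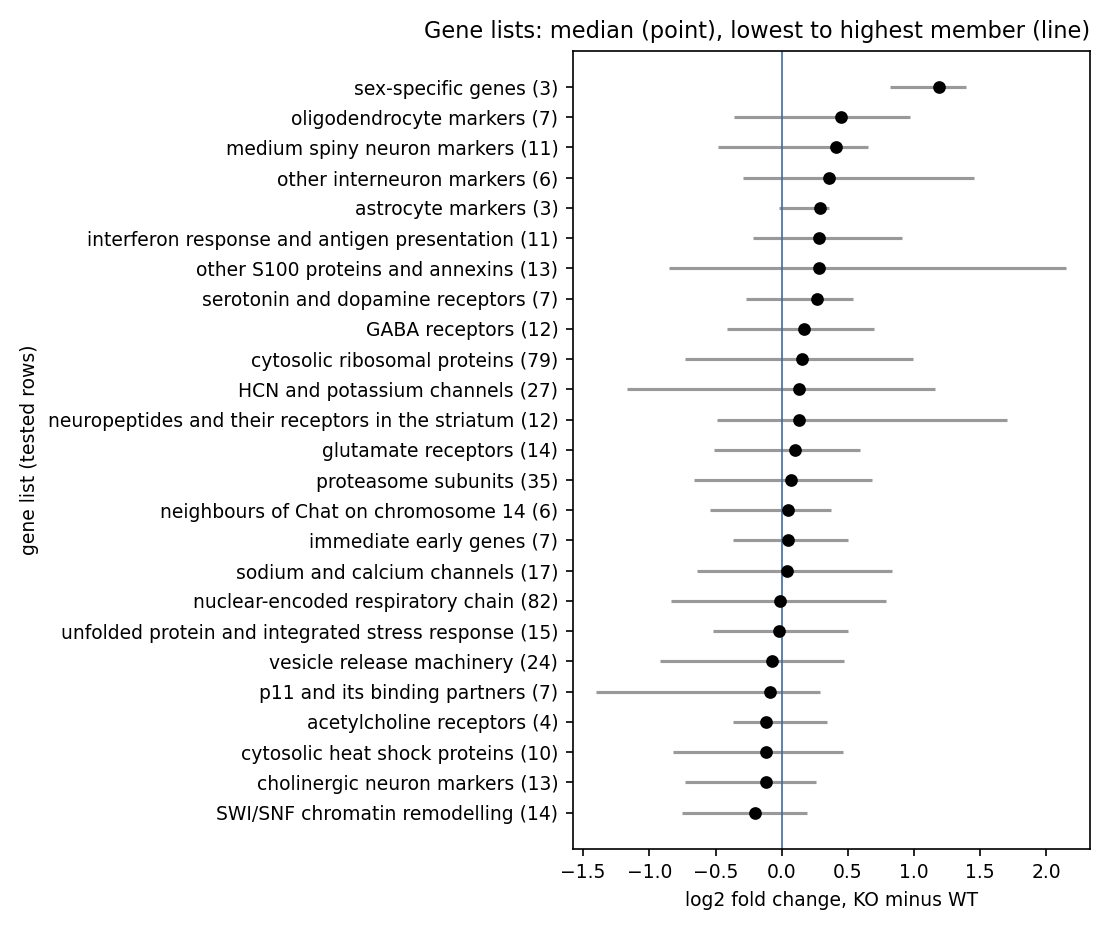
Log2 fold change (KO minus WT) of the 25 tested gene lists, with the median as a point and the lowest to highest member as a line; the number of tested rows stands in brackets. Medians ran from -0.20 for the SWI/SNF list to 1.19 for 3 Y-linked genes, and the other S100 proteins and annexins reached 2.15.

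The authors' deposited table held 113 genes, 54 higher and 59 lower in KO. Of these genes, 103 had a row among the FPKM values and 99 were tested, and the direction in the authors' deposited table was that of the limma fold change in 99 of the 99. The limma test called 82 of the 113. The deposited genes were chosen on these same libraries and are no independent evidence of direction. With predicted genes passed over, the largest log2 fold changes in the authors' deposited table were those of Adamts13 (9.43), Itga4 (5.33), Onecut2 (3.70), Cdr1 (3.44) and Nup98 (3.12), and the lowest those of Zfp352 (-10.72), Cspg4 (-3.93), Kcnk12 (-2.51), Rhov (-2.08) and Gfod2 (-1.92). Values near 0 set the size of several of these: Itga4 stood at 0.0 in WT and 0.1 to 0.2 FPKM in KO, and Cspg4 at 0.7 to 1.1 in WT and 0.0 to 0.1 FPKM in KO. S100a10 had -1.40 and an adjusted p of 2.5e-07 in the authors' deposited table. Of the called symbols, 85 were not in that table, among them Nme7, Srsf4, Mt3, Prr12, Cdkn2d and Tac2.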

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

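The tests on the KO1 pattern were chosen after the result was seen. Each KO group of 4 values was examined for a single value far from the other 3, in 125 sets of values, and 6 stood apart, where chance alone would give about 6.25. KO1 held 3 of them: Cacna1d at 2.9 FPKM, Ttr at 6.9 FPKM and Psmb8 at 1.3 FPKM, the first 2 above and the last below the other KO libraries. KO4 held Cdr1 at 632 FPKM and Drd2 at 857.8 FPKM, both above the others. KO2 held Itga4 at 0.2 FPKM, above the others by the rounding step. The 3 WT libraries were not examined in this way. WT1 had the most rows listed at 0, 9698, while the other libraries had from 8661 in KO1 to 9042 in KO2.

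KO1 had the highest values of several genes of other cells, such as Sst (51 FPKM), Penk (50.7 FPKM) and Mbp (33.5 FPKM), while Rasd2, a marker of medium spiny neurons, had its lowest value there (82.3 FPKM). A difference in the scaling of KO1 is argued against, since the median log2 ratio of KO1 to the mean of KO2 to KO4 was -0.04 over 10089 tested rows and 1.26 over 24 markers of medium spiny neurons, other interneurons and oligodendrocytes. More RNA of other cells in KO1 may account for it: the lowest of the 3 list medians was 1.22. This stays open, since cholinergic markers had a median of -0.08 with an upper quartile of 0.09, and the markers tested were those that showed the pattern. Astrocyte markers had a median of -0.05 over the 3 rows that reached the filter. Below the filter, Slc1a3, Aqp4, Gjb6, Gja1, Gfap and Sox9 had their highest value in KO1, at 0.8 to 3 FPKM. Aldh1l1, Fgfr3 and Slc7a10 had theirs in WT1, and these low values were not tested. No biological explanation was tested, because the design separates KO1 from the other KO libraries by nothing but its number.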

How the results depend on the processing

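The removal of GC and length trends and the term for Y-linked RNA were chosen after seeing the data; the other alternatives were fixed before. S100a10 kept its direction in 19 alternatives (-1.58 to -1.22) and passed in 16, with adjusted p from 0.00023 to 0.092. The count of 176 calls (98 higher, 78 lower) stayed within 1.5 times with either pseudocount, a mean of at least 5 FPKM, quantile normalization, median centring, robust variances and summed rows. It was 83 (51 and 32) without a filter, where 14967 rows were tested, 100 (63 and 37) without trend, and 1689 (847 and 842) with array weights. The term for Y-linked RNA gave 139, 50 of them lower, and 101 were among the 176. The cause of these shifts was not tested. Leaving out 1 library gave 28 to 376 calls (24 to 222 higher, 4 to 154 lower) and -1.58 to -1.22 for S100a10, partly by construction, since 6 libraries remain. The replicate block on WT1-3 and KO1-3 gave 18 calls (15 and 3, 83.3% higher) and S100a10 at -1.22 (adjusted p = 0.092), with 2 residual degrees of freedom. With each gene's group mean removed, same-numbered libraries correlated across genes at -0.22, 0.02 and -0.26. These values gave no sign of a pairing by number, but so few pairs cannot exclude one. The 99 genes with the authors' direction were 99 to 100 with a library left out. At the preset correlation, lists called by camera went from 0 to 1 (SWI/SNF) without a filter, with a mean of at least 5 FPKM and with the Y-linked term. They went to 2 (SWI/SNF and ribosomal proteins) with array weights, and to 0 to 3 with a library left out. With all libraries and an estimated correlation camera called 0, and fry called 1. The test planned for counts was not run, since the values are not counts, and unknown depth limits the genes of low FPKM. Beside S100a10, 27 named genes passed; 9 of them lost the call without a filter (Tac2, Snhg1, Cdkn2d, Hcn2, Gabrg3, Smarce1, Smarca4, Ndufa13 and Rps25), 6 without trend (Cdkn2d, Hcn2, Gabrg3, Smarce1, Smarca4 and Ndufa13), 8 with the Y-linked term (Tac2, Cdkn2d, Gabrg3, Rims1, Smarce1, Smarca4, Ndufa13 and Rps25), 5 with GC and length trends removed (Tac2, Hcn2, Gabrg3, B2m and Smarca4), 17 with the block and 1 with pseudocount 5 (Tac2), and 0 reversed. Directions turned in 10 genes and 11 lists that had not passed and did not pass then, at adjusted p of at least 0.1 and of untested cause. Among genes, Grm5 was 0.01 with pseudocount 5 and 0.02 with the block. With array weights Chrm4 was 0.06, Slc17a7 -0.25, Pdgfra -0.15, Nr4a2 0.00 and Grin2a -0.10. With GC and length trends removed Dlc1 was 0.02, Chrm4 0.00, Kcnk3 0.21 and Aldoc 0.03, and Dlc1 was 0.02 with the Y-linked term. With a library left out the ranges were -0.16 to 0.05 for Chrm4, -0.13 to 0.17 for Pdgfra, -0.07 to 0.02 for Aldoc, -0.25 to 0.00 for Dlc1, -0.28 to 0.13 for Grm5, -0.13 to 0.01 for Kcnk3 and -0.25 to 0.00 for Rgs5. For lists the direction is camera's and the value the median, so the signs can differ. Glutamate receptors were 0.10 with fry and 0.09 with GC trends removed, and respiratory chain genes -0.01 with fry and 0.09 with array weights. Immediate early genes were 0.08 with pseudocount 0.1, 0.02 without a filter, 0.00 with array weights, -0.11 with the block and 0.00 with the Y-linked term. Acetylcholine receptors were 0.03 without a filter. HCN and potassium channels were 0.13 at a mean of at least 5 FPKM, -0.02 with array weights and 0.12 with the block. Neighbours of Chat were 0.05 at a mean of at least 5 FPKM, -0.05 with array weights and 0.05 with GC trends removed. Proteasome subunits were 0.00 with quantile normalization and -0.03 with GC trends removed, sodium and calcium channels 0.06 with GC trends removed, and ribosomal proteins -0.01 with the block. Medium spiny neuron markers were 0.04 with array weights and 0.33 with the Y-linked term. With a library left out the ranges were -0.09 to 0.10 for the respiratory chain, 0.04 to 0.19 for neighbours of Chat, -0.09 to 0.21 for HCN and potassium channels, -0.11 to 0.24 for immediate early genes, -0.17 to 0.12 for sodium and calcium channels, -0.12 to 0.20 for glutamate receptors, -0.03 to 0.14 for the proteasome, 0.05 to 0.67 for medium spiny neuron markers, -0.22 to 0.01 for heat shock proteins and -0.01 to 0.32 for ribosomal proteins.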

Other observations

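The tests on library numbers, and on the called rows that no longer passed with GC and length trends removed, were chosen after the result was seen; the other tests below were written down before their results. Of 15 genes of the unfolded protein and integrated stress response, 0 passed with limma over all rows or adjusted over the list alone, and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.64, fry adjusted p = 0.60), while fry's mixed test, which asks for change in either direction, called the list (adjusted p = 0.0038). The mixed test does not compare the list with other genes, and 1899 of all 10089 tested rows had an unadjusted limma p under 0.05. Dnajb9, a chaperone partner of the endoplasmic reticulum, had a log2 fold change of 0.50 and Ddit3, a stress-induced transcription factor, one of -0.40 (limma adjusted p = 0.13 and 0.19). Of 10 heat shock genes 0 passed with limma and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.60, fry 0.94). The list was named cytosolic but also held the mitochondrial Hspd1 and Hspe1. Dnajb1 stood at 106 ± 43.8 FPKM in WT (SD, n = 3) and 60.4 ± 24.9 in KO (SD, n = 4). Immediate early genes gave 0 of 7 with limma, also at an unadjusted p under 0.05 (camera adjusted p = 0.98, fry 0.97), Egr1 with 6.2 ± 0.608 FPKM in WT and 10.3 ± 6.6 in KO. Of 35 proteasome subunits 0 passed over all rows with limma and 7 had an unadjusted p under 0.05 (camera adjusted p = 0.87, fry 0.96), while Psmd3 (-0.66) and Psmb10 (-0.62) passed when adjusted over the list alone.

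Tac2 was the 1 of 12 tested neuropeptide and receptor genes that passed (camera adjusted p = 0.64 for the list), and Crhr1, a receptor for corticotropin-releasing hormone, had a log2 fold change of -0.49. Of 6 tested neighbours of Chat on chromosome 14, 0 passed with limma and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.93, fry 0.96), with Parg at -0.54. The 3 tested Y-linked genes differed by library more than by group. Ddx3y stood at 4.8 FPKM in WT1 and 7, 5.7 and 8.1 FPKM in KO1, KO3 and KO4, and was listed at 0.0 in WT2, WT3 and KO2. Eif2s3y and Uty were likewise listed at 0.0 in WT2, WT3 and KO2. As a list the 3 genes had 0 members past the threshold with limma, also at an unadjusted p under 0.05, and a camera adjusted p of 0.31 (0.86 with an estimated correlation), and without WT1 or KO2 it was 0.017 and 0.0081 at the preset correlation.

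The 176 called rows were weighed against chance, GC content and the library numbers. Of the 35 splits of the 7 libraries, 1, the real one, gave as many calls, and the highest of the others gave 3. Chance can therefore be excluded at the 0.05 level for the number of calls. The splits say nothing about single rows, many of whose calls depended on 1 library. The called rows higher in KO had a median GC content of 43.8% and those lower in KO one of 56.4%, against 49.4% over all tested rows, but trends with GC content and length are argued against as the whole cause, since 54.6% of 174 called rows still passed once they were removed. For the other 79 rows they may be the cause and cannot be told apart from genotype: all 79 kept their direction, and the median size of the change went from 0.83 to 0.60 (log2) at median SEs of 0.17 and 0.16. The calls ended with a smaller difference in 74 of the 79 rows and without one in the other 5, and the difference was also smaller in 65 of the 95 rows that still passed. The library numbers in the file header run from 83 to 113 in WT and 210 to 222 in KO, with 0 KO numbers below the highest WT number. The labels do not say what the numbers stand for. A batch behind them therefore stays open for the called rows other than S100a10, whose fall the design gives. Sex is open in part, since Y-linked RNA was present in 1 of 3 WT and 3 of 4 KO libraries. For the called rows other than S100a10, Cre itself, carried by the KO mice alone, cannot be told apart from the deletion.

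Multi-copy predicted genes in 2 clusters, chosen after their values were seen, were higher in KO: 16 of 26, on chromosome 2 (175275125 to 178078476) and chromosome 14 (3049285 to 7568566). The predicted gene 0610010B08Rik was listed at 0.1 FPKM in each WT library and at 15.8, 16.5, 16 and 13.1 FPKM in KO1 to KO4. Whether shared reads were assigned differently in WT and KO cannot be decided here. The clusters were chosen after their values were seen, so their share of calls is no fair measure for other families. Many cluster genes also share nearly all of their sequence with other genes, so their calls are not independent. Multi-copy genes elsewhere needed to share only 20%. Of 762 multi-copy genes elsewhere, 1.05% were called higher (upper 95% bound 2.06%), against 61.5% in the clusters and 0.684% of 9205 single-copy genes. A general difference in how shared reads were assigned stays open (one-sided Fisher exact p = 0.17 for multi-copy genes elsewhere against single-copy genes). A segment carried with the Cre allele at Chat may account for the chromosome 14 cluster, but it stays open: 1 of 194 single-copy genes of that chromosome between 8 and 60 Mb was called (one-sided Fisher exact p = 0.94), and such a segment need not change them. A copy number difference between the mice of the 2 groups was not tested and would need their DNA.

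Of the largest changes, 5 of 15 symbols with at least a 4-fold change were not in the authors' deposited table, namely Nme7, Srsf4, Prr12 and the predicted genes Gm14430 and Gm5741, the last pair chosen after their values were seen. Blzf1, next to Nme7, had 3.5 ± 0.917 FPKM in WT and 5.2 ± 0.927 in KO, and Mecr, next to Srsf4, 5.7 ± 0.2 and 5.95 ± 2.21 FPKM, both chosen after their values were seen. Atp1b1 and Tmem200b were looked up as well but had no tested row under these symbols, so not all neighbours are covered. An effect of quantification or of overlapping genes on the FPKM values of Nme7 and Srsf4 stays open, since read counts were not analysed here.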
